A study of Oryza sativa with 8 samples.

How the data were processed

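RNA was sequenced from the coleoptile, the sheath that covers the shoot of a grass seedling, and from the first leaf of rice (cultivar Nipponbare). Coleoptiles came from seedlings 2 days old and first leaves from seedlings 3 days old, so tissue and age cannot be separated. Seeds were kept in water at 37 °C for 24 h and seedlings were grown at 28 °C in continuous white light. Of the 8 libraries, 4 came from seedlings moved to simulated shade for 1 h, with red light at 16, blue light at 1.3 and far-red light at 48 µE per square metre per second. Shade of this kind has less red than far-red light. Each of the 4 groups has 2 libraries. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

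The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 55801 locus identifiers and a text annotation for each. Reads were paired and 150 bp long, per the labels. The submitters' processing notes name bcl2fastq 2.16.0.10, Trim Galore 0.3.7, FastQC 0.11.2, TopHat2 2.0.14, Bowtie2 2.2.3 and Cufflinks, Cuffnorm and Cuffdiff 2.2.1. The genome build and the annotation release are not given in the sources used here. Gene names are the locus identifier and the annotation text of the table, and no coordinates are given, because the locus identifiers could not be tied to a build. Chromosome numbers were read from the locus identifiers.

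All values were deposited as FPKM by the authors, so no count model was used. FPKM summed to between 696059 and 808054 per library, and between 26693 and 28127 loci were above 0. Total fragment numbers are not given. The step between low values, which is what 1 fragment is worth, put the relative depth between 0.829 and 1.38 times that of coleoptile shade replicate 1, with 36.3% to 42.7% of low loci at that step in the 7 other libraries. Of the loci, 22903 were at 0 in every library. An exact 0 can be a failed estimate: 20 loci with a median of at least 10 FPKM were listed at 0 in some library. Such values are called listed at 0, and no fold is given against a group at 0.

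Values were tested as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, on the 21014 loci with a mean of at least 1 FPKM over the 8 libraries. Fold changes are on this log2(FPKM + 1) scale, which understates the change of low genes. The 4 groups were fitted together as a cell means model, so that they share 1 estimate of the spread, with empirical Bayes moderation and an intensity trend. The fit had 4 residual degrees of freedom and 3.26 prior degrees of freedom. Contrasts were shade minus white light in each tissue, the difference of the 2 shade responses (first leaf minus coleoptile) and first leaf minus coleoptile in white light. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Errors of fold changes are limma's standard errors (SE), and errors of FPKM means are SD with n = 2.

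Before the data were examined, 27 gene lists were fixed as keywords in the annotation text or as locus identifiers. They cover hormones, light signalling and the clock, growth and cell walls, photosynthesis, stress, ribosomal proteins and markers of seed and root tissue. A keyword list holds what the annotation calls by that name. The root list (nitrate transporters, aquaporins, silicon transporters and secreted peroxidases) holds families that shoots also express. The seed list takes in all loci annotated with a cupin domain, as seed storage and LTP family or as late embryogenesis abundant. Of its 298 loci, 128 passed the filter in these shoot libraries, so its members are not markers of seed tissue alone. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Estimates ran from -0.01 (auxin response factors) to 0.58 (abscisic acid genes), and they are the same in every contrast. With all libraries, the estimates and the tests that use them rest on 4 residual degrees of freedom. For heat shock genes the estimate was 0.0097, under the preset, so a larger correlation does not account for the loss of their calls. A call lost with an estimated correlation therefore does not show that a list was unchanged. The rule for named genes, also fixed then, took the 6 highest and 6 lowest fold changes among called loci whose libraries did not overlap and whose annotation names a function, and up to 3 called members per list. Where fewer than 5 loci were called, it took the 5 highest and 5 lowest fold changes among the 50 smallest p-values, as loci that did not pass. Phytochromes were always reported. List members named for passing when adjusted over the list alone, the other called loci of short lists, the chromosome 10 loci and the root cap loci were chosen after their values were seen.

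The model was tested on simulated data with 1 spread per gene, the same in all 8 libraries (21014 genes, 5 rounds of 200 changed genes). For the coleoptile comparison it recovered 25.7% of 2-fold, 93.7% of 4-fold and 97.9% of 8-fold changes, with 7.9% false calls. For the first leaf comparison it recovered 27.5%, 94.9% and 98.5% of them, with 5.16% false calls. Changed genes came from a middle range of level, so these rates do not cover low loci. Nor do they cover the wider spread of the white light coleoptile replicates (SD of their log2 difference 0.788, against 0.350 to 0.413 in the other groups). Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, quantile normalization, scaling to equal medians, a fit to the libraries compared only, no trend, a replicate block and leaving out each library. Library weights, the tissue comparison in the shade libraries, list tests without 1 library (with the preset and an estimated correlation) and the mean shade response of both tissues were added after the data were seen. Leaving out 1 library leaves 1 in its group, and that group then adds nothing to the pooled spread. Without a white light coleoptile library the spread came only from the other groups. The p-values and calls of such fits therefore do not measure the wider spread of the white light coleoptile. Figures were drawn with matplotlib from Python.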

Results

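The data are 8 transcriptome libraries, 2 for each combination of tissue (coleoptile or first leaf) and light (white light or 1 h of shade). Tissue gave the main axis, with 56.3% of the variance between coleoptile and first leaf libraries. Replicates of 3 groups correlated at r = 0.975 to 0.982 across loci. Those of the white light coleoptile correlated at r = 0.914, and 3167 loci were over 2-fold apart between them, against 299 between the shaded coleoptile replicates. Coleoptile white light replicate 1 lay alone on the second axis (19.4% of the variance). In it, 1841 loci were over 2-fold above the mean of the 3 other coleoptile libraries, which is 8.76% of the tested loci. They included 29 of 70 WRKY genes, 37 of 99 AP2 genes and 15 of 25 jasmonate genes, families of transcription factors and signalling genes best known from stress and wounding.

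**Figure D1:**
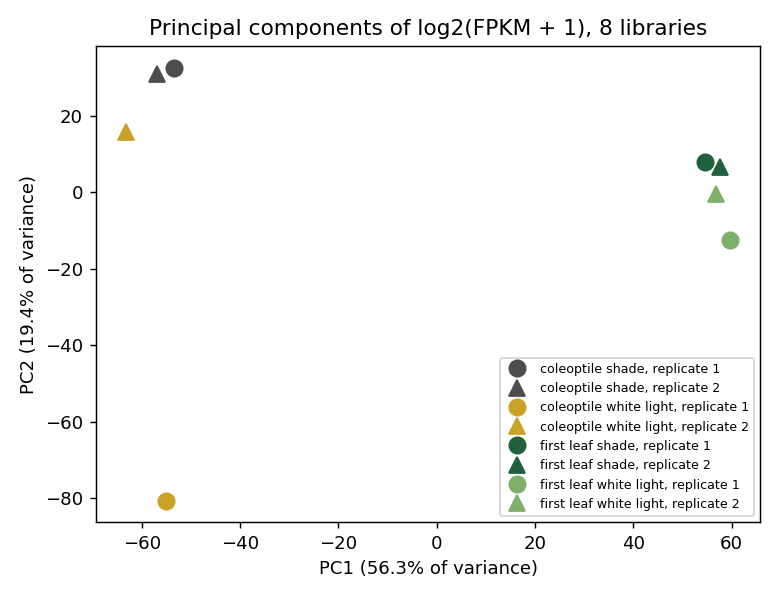
Principal components of log2(FPKM + 1) over the 21014 tested loci; each point is 1 library, its colour the group and its shape the replicate (circle 1, triangle 2), and the axes give component scores with their percent of variance. The first component (56.3%) parts the tissues, and coleoptile white light replicate 1 stands alone on the second (19.4%).

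Which transcripts of the coleoptile differed after 1 h of shade was tested first. A set of neighbouring loci on chromosome 10 annotated as glycine-rich cell wall proteins, structural proteins that are laid down in the wall of extending and vascular cells, was on in the shaded coleoptile and close to 0 elsewhere. LOC_Os10g31530 was at 19.0 and 26.7 FPKM in the shaded libraries and listed at 0 in both white light libraries (limma adjusted p = 0.00383). LOC_Os10g31680 was at 12.5 and 11.9 FPKM in shade and listed at 0 in white light (adjusted p = 0.00383). LOC_Os10g31660 rose by 5.53 ± 0.41 (SE) on the log2 scale, to a mean of 57.5 ± 30.6 FPKM (SD, n = 2) (adjusted p = 0.0116), and LOC_Os10g31640 rose by 3.29 ± 0.28 (adjusted p = 0.0192). LOC_Os10g31670 and LOC_Os10g31730 in the same stretch, annotated as retrotransposon proteins, were at 10.6 and 10.9 FPKM and at 6.59 and 9.48 FPKM in shade and listed at 0 in white light (adjusted p = 0.00398 and 0.01505). LOC_Os08g14200, a glycosyl hydrolase of family 16, the family of enzymes that cut and join xyloglucan, rose by 2.57 ± 0.27 (adjusted p = 0.0490).

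Those 7 loci were higher in shade, and 2 were lower. LOC_Os03g46090, annotated with an endonuclease/exonuclease/phosphatase domain, fell by 1.74 ± 0.17 on the log2 scale, from 24.4 ± 0.34 to 6.60 ± 0.501 FPKM (SD, n = 2; adjusted p = 0.0422). LOC_Os04g54220, annotated as an expressed protein, fell by 2.39, from 10.03 ± 2.24 to 1.09 ± 0.0763 FPKM (adjusted p = 0.0422). At an unadjusted p under 0.05 there were 2083 loci (877 higher, 1206 lower), where 1051 would pass by chance. With libraries scaled to equal medians the split was 8 higher and 5 lower. The called count was 232 (138 higher, 94 lower) without coleoptile white light replicate 1, 1739 (407 higher, 1332 lower) without replicate 2, and 0 to 3 without any of the 6 other libraries. All 9 called loci remained without either white light coleoptile library. Counts from fits without a white light coleoptile library rest on the spread of the other groups, and not on that of the white light coleoptile. Limma called 0 loci with a pseudocount of 0.1, with a mean of at least 5 FPKM or in a fit to the coleoptile libraries only, and 68 (56 higher, 12 lower) with no filter.

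Of the 24 loci from LOC_Os10g31500 to LOC_Os10g31740, 12 are annotated as glycine-rich and 15 exceeded 1 FPKM in some library. In the whole table, 13 loci reached 3 FPKM in both shaded coleoptile libraries and stayed under 0.5 FPKM in the 6 others, and 7 of them lie in this stretch. The others include an expansin (LOC_Os01g16770, 3.05 and 3.22 FPKM), a wall-loosening protein, and the glucan synthase CSLF3 (LOC_Os07g36750, 3.14 and 4.36 FPKM). In white light 2 loci met the same bounds for the coleoptile, and 0 did for either first leaf group. Reads of such similar neighbouring genes can be split between copies, so the value of each copy is uncertain. Loci annotated as a root cap and late embryogenesis related family, chosen after their values were seen, were high in the same libraries: 5 of the 7 above 0 were higher in both shaded coleoptile libraries than in the 6 others, with LOC_Os01g73730 at 2.35 and 3.67 FPKM against at most 0.314 FPKM elsewhere.

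**Figure D2:**
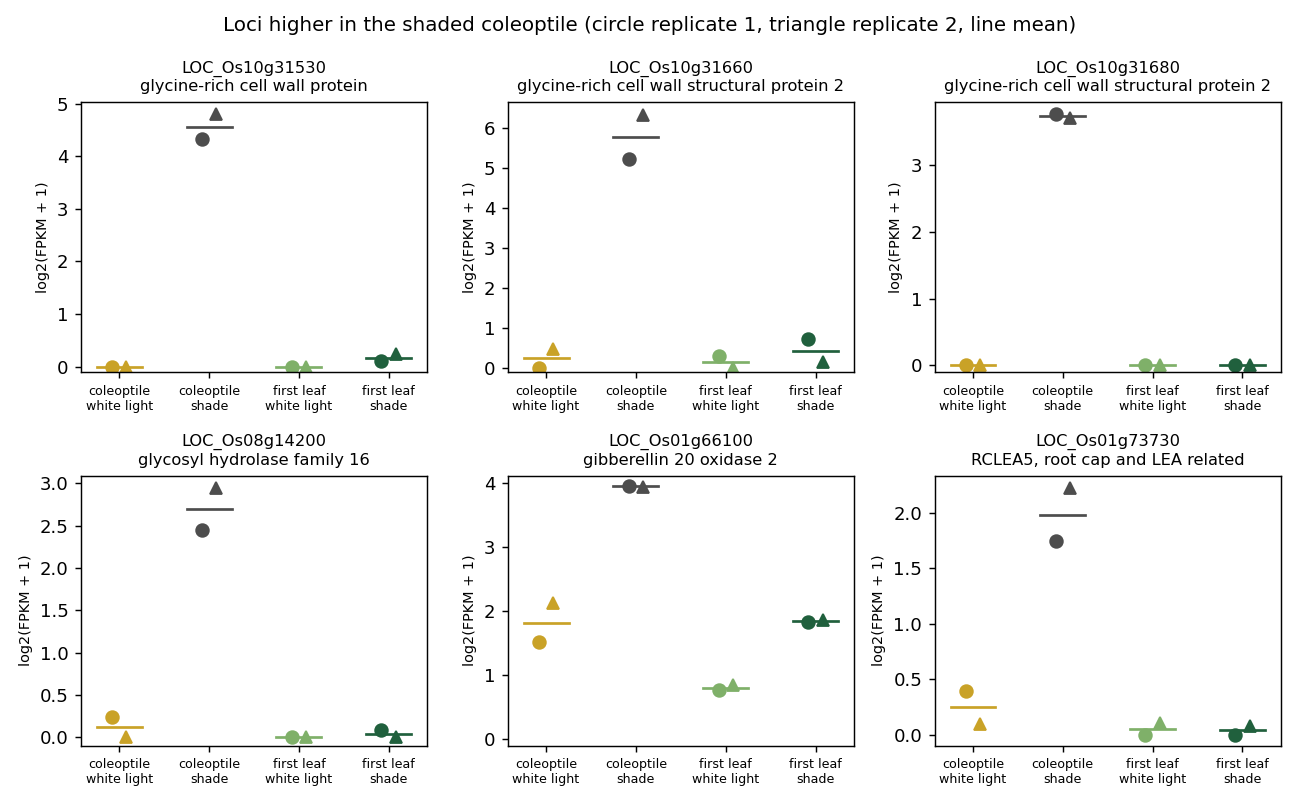
Level of 6 loci as log2(FPKM + 1) in each library, by group; circles are replicate 1, triangles replicate 2 and lines the mean of the 2. The glycine-rich loci LOC_Os10g31530, LOC_Os10g31660 and LOC_Os10g31680 and the root cap locus LOC_Os01g73730 are high in both shaded coleoptile libraries, and gibberellin 20 oxidase 2 (LOC_Os01g66100, adjusted p = 0.0620) did not pass the test.

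Growth hormone genes of the coleoptile did not pass over all loci, and several passed when adjusted over the list alone. Gibberellin 20 oxidase 2 (LOC_Os01g66100), of a family that makes the precursors of active gibberellin, was at 14.4 ± 0.135 FPKM in shade and 2.61 ± 1.04 FPKM in white light (SD, n = 2; log2 change 2.12, adjusted p = 0.0620). Of 57 gibberellin genes, 0 passed over all loci, and 4 rose and 3 fell adjusted over the list alone. Those lower included the gibberellin 2-beta-dioxygenases LOC_Os01g11150, LOC_Os01g55240 and LOC_Os04g44150, enzymes that inactivate gibberellin, with log2 changes of -1.43, -2.36 and -2.06. The list as a whole was not called (camera adjusted p = 0.778), and its median of 0.12 and mean of -0.05 differed in sign. In the fit without coleoptile white light replicate 1, which leaves 1 white light coleoptile library, the gibberellin median was 0.38. Of 22 HD-Zip homeobox genes, a family with known shade markers, 0 passed over all loci and 3 rose adjusted over the list alone, LOC_Os06g04870 by 1.04, LOC_Os08g36220 by 1.11 and LOC_Os10g23090 by 1.21 on the log2 scale. The HD-Zip list was called upward (median 0.33, camera adjusted p = 0.00826). It had adjusted p = 0.609 with an estimated correlation. Among 38 SAUR genes, small auxin-induced transcripts, 29 had a positive log2 change and 1, LOC_Os09g37350 (OsSAUR40), rose by 1.25 adjusted over the list alone. SAUR genes (median 0.45, adjusted p = 0.0132) and 18 auxin synthesis and transport genes (median 0.20, adjusted p = 0.0361) were called upward. The SAUR list had adjusted p = 0.680 with an estimated correlation and the auxin list adjusted p = 0.609, and quantile normalization ended both calls (adjusted p = 0.0978 and 0.0836). They also ended without coleoptile white light replicate 1 (adjusted p = 0.909 and 0.326), with a SAUR median of -0.05, and the HD-Zip list had adjusted p = 0.0187 with the preset correlation and adjusted p = 0.798 with an estimated correlation.

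Of 29 expansins, 0 passed over all loci and 2 rose adjusted over the list alone, LOC_Os03g06000, at 5.30 ± 0.036 FPKM in shade and 1.23 ± 0.116 in white light (SD, n = 2), and LOC_Os05g19600, at 2.61 and 7.40 FPKM in shade and listed at 0 in white light. Of 88 cell wall enzymes, LOC_Os08g14200 rose over all loci, and another glycosyl hydrolase of family 16, LOC_Os04g51460, was lower when adjusted over the list alone (log2 change -2.63). The list was not called with all libraries (camera adjusted p = 0.804). Without coleoptile white light replicate 1, 3 cell wall enzymes rose and 1 fell over all loci, and the list (median 0.21) had adjusted p = 0.0187, and adjusted p = 0.798 with an estimated correlation. In the light signalling list, 0 of 48 passed over all loci, and 4 rose and 1 fell adjusted over the list alone, among them the B-box genes LOC_Os06g49880 (1.49) and LOC_Os02g43170 (-1.36), a family of light-regulated transcription factors. Adjusted over the list alone, 1 of 128 seed list genes (LOC_Os02g44310, of the protease inhibitor and LTP family, 4.77) and 1 of 106 root list genes (LOC_Os03g02939, a peroxidase, 2.53) passed.

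Stress and defence families had negative medians in the shaded coleoptile. Of 25 jasmonate genes, 0 passed over all loci and 9 fell adjusted over the list alone, among them the ZIM domain genes LOC_Os10g25230 and LOC_Os03g08310 (log2 changes of -3.39 and -3.42), a family of jasmonate repressors, and 12-oxophytodienoate reductase LOC_Os06g11240 (-2.98), of jasmonate synthesis. Camera called the jasmonate list (median -0.61, adjusted p = 9.61e-08), 70 WRKY genes (median -0.35, adjusted p = 9.61e-08) and 99 AP2 genes (median -0.13, adjusted p = 8.39e-05). Each had adjusted p = 0.609 with an estimated correlation. Adjusted over the list alone, 8 WRKY genes fell, and 16 AP2 genes fell and 3 rose. WRKY28 (LOC_Os06g44010) was at 174 FPKM in white light replicate 1, 26.0 FPKM in replicate 2 and 0.663 ± 0.0475 FPKM in shade, and AP2 gene LOC_Os02g52670 at 523, 111 and 7.29 ± 1.55 FPKM (SD, n = 2). Without white light replicate 1 the camera adjusted p was 0.000985 for WRKY (median -0.22), 0.000961 for jasmonate (median -0.42) and 0.0805 for AP2 genes, and each had adjusted p = 0.798 with an estimated correlation. In that fit 5 AP2 genes, 2 WRKY genes and 2 heat shock genes fell over all loci and 1 WRKY gene rose, where 0 passed with all libraries. Camera also called the 106 genes of the root list (median 0.21, adjusted p = 0.00271), 112 heat shock genes (median -0.07, adjusted p = 0.0132) and 290 ribosomal protein genes (median -0.16, adjusted p = 0.00142). With an estimated correlation these had adjusted p = 0.609, adjusted p = 0.609 and adjusted p = 0.983. Quantile normalization ended the ribosomal call (adjusted p = 0.355). Without coleoptile white light replicate 1 the root (adjusted p = 0.0805) and ribosomal (adjusted p = 0.616) calls ended, the ribosomal median moved to 0.07, and the heat shock list (median -0.15) had adjusted p = 0.0177 with the preset correlation and adjusted p = 0.798 with an estimated correlation. Median, mean and camera direction differed in sign for gibberellin, brassinosteroid, ethylene, cytokinin, abscisic acid, chlorophyll synthesis and flavonoid genes, none of them called. For the 18 lists not called, camera gave adjusted p from 0.357 to 0.930.

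In the first leaf, 1 h of shade went with lower early light-induced and heat shock transcripts, none of which passed the threshold. Early light-induced proteins bind pigment in chloroplasts under excess light. LOC_Os07g08160 was at 178 ± 57.5 FPKM in white light and 11.05 ± 1.75 in shade (SD, n = 2; log2 change -3.86 ± 0.35 SE, limma adjusted p = 0.0570). LOC_Os01g14410 (log2 change -2.98) and LOC_Os07g08150 (-2.73) had the same adjusted p. Heat stress transcription factor LOC_Os03g06630 (-3.05) and small heat shock protein LOC_Os06g14240 (-2.90) also had an adjusted p of 0.0570, and LOC_Os01g62060, of an unnamed plant-specific family, was at -3.52 (adjusted p = 0.0931). The highest log2 changes among the 50 smallest p-values were those of LOC_Os04g54310 (2.50, an expressed protein), LOC_Os01g19820 (2.29, a universal stress protein), LOC_Os10g18820 (2.10, a dirigent protein), LOC_Os06g48500 (2.00, an expressed protein) and LOC_Os07g04410, a cytochrome P450 annotated as 90C1, a family of brassinosteroid synthesis, with adjusted p from 0.0720 to 0.1996. LOC_Os07g04410 was listed at 0 in both white light first leaf libraries and at 3.36 and 2.83 FPKM in shade.

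Limma called 0 first leaf loci, with 1152 at an unadjusted p under 0.05 (632 higher, 520 lower) where 1051 would pass by chance. Leaving out either white light coleoptile library raised the number of calls and kept the first leaf fold changes, whose means use no coleoptile library. Only the spread shared by the 4 groups changed, so the 0 calls rest in part on pooling with the white light coleoptile replicates. A fit to the first leaf libraries only, with fewer samples, also gave 0. No filter gave 14 calls (7 higher, 7 lower) and a mean of at least 5 FPKM gave 5. Scaling to equal medians gave 12 calls (3 higher, 9 lower) and quantile normalization 14 (3 higher, 11 lower).

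**Figure D3:**
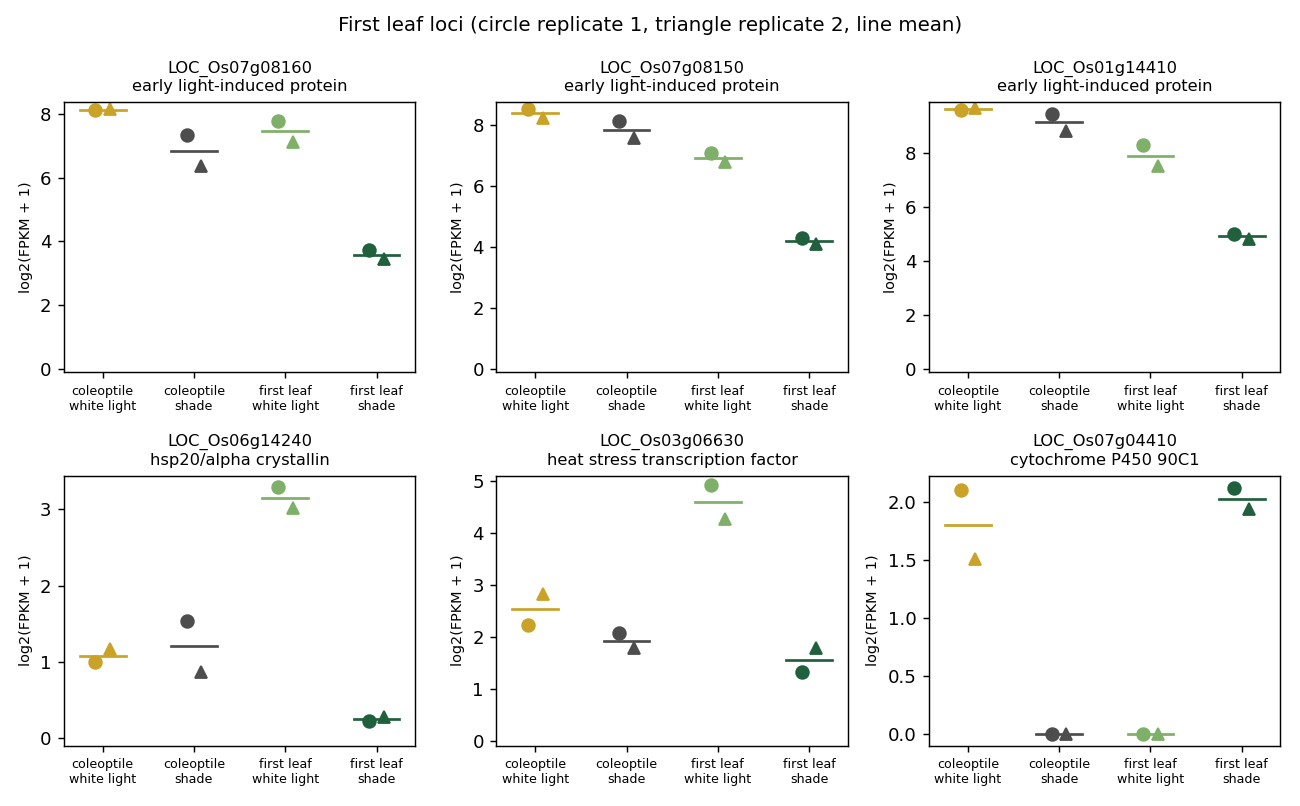
Level of 6 loci as log2(FPKM + 1) in each library, by group; circles are replicate 1, triangles replicate 2 and lines the mean of the 2. Early light-induced protein LOC_Os07g08160 averages 178 FPKM in white light first leaves and 11.05 FPKM in shaded ones, and none of the 6 passed the first leaf test.

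Heat shock genes as a list had a negative median in the shaded first leaf, called by camera with its preset correlation and not with an estimated one. Of 112 measured, 74 had a negative log2 change and 12 fell adjusted over the list alone, among them LOC_Os06g14240, the mitochondrial heat shock protein LOC_Os02g52150 (log2 change -1.72) and the DnaK chaperones LOC_Os03g16860 (-2.51) and LOC_Os01g62290 (-2.31). None of the 112 passed over all loci with all libraries, and 8 fell without coleoptile white light replicate 1 (camera adjusted p = 1.63e-07, and adjusted p = 0.417 with an estimated correlation). Camera called the list (median -0.18, adjusted p = 3.13e-08), and so did fry (adjusted p = 0.0325). With an estimated correlation the list had adjusted p = 0.0966, the smallest of any list in any comparison. That estimate was 0.0097, under the preset of 0.01, so a larger correlation does not account for the lost call. Over the 4 comparisons, 0 of the 32 camera calls held with an estimated correlation, and the directional test of fry called the heat shock list alone. The mixed test of fry, for changes in either direction, called 6 lists for coleoptile shade and 4 for first leaf shade. It called 3 for the difference of responses and 23 for tissue. Light signalling genes had fry mixed adjusted p = 0.0106, 0.00167, 0.00693 and 1.34e-05 in that order. In the light signalling list, 5 of 48 rose and 7 fell adjusted over the list alone, the latter led by the early light-induced genes, and the list was not called (camera adjusted p = 0.0978). Over all loci 0 of the 48 passed, and 3 fell without that library. Of 12 clock genes, 0 passed over all loci and the response regulator receiver genes LOC_Os07g49460 and LOC_Os03g17570 fell adjusted over the list alone (log2 changes of -1.02 and -0.88). Chlorophyllide a oxygenase LOC_Os10g41780, which makes chlorophyll b, fell adjusted over the list alone, as 1 of 8 (log2 change -1.29).

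Other lists were called in both directions in the first leaf, and 0 of their members passed over all loci. Of 60 cell cycle and histone genes, 51 had a negative log2 change (median -0.53, camera adjusted p = 8.30e-06), as had 234 of 290 ribosomal protein genes (median -0.23, adjusted p = 1.20e-05), 10 of 14 cytokinin genes (median -0.22, adjusted p = 0.0302) and 8 of 12 clock genes (median -0.07, adjusted p = 0.0237). With an estimated correlation they had adjusted p = 0.762, adjusted p = 0.788, adjusted p = 0.762 and adjusted p = 0.762. Lists called upward were the root list (median 0.28, adjusted p = 2.15e-05), cell wall enzymes (median 0.20, adjusted p = 0.00116), HD-Zip genes (median 0.26, adjusted p = 0.00116), Aux/IAA genes (median 0.26, adjusted p = 0.0129), and gibberellin, SAUR and WRKY genes (medians 0.20, 0.24 and 0.19, each with adjusted p = 0.0203). With an estimated correlation their adjusted p ran from 0.541 to 0.788: for the root and HD-Zip lists adjusted p = 0.541, for the gibberellin list adjusted p = 0.788 and for the others adjusted p = 0.762. In the HD-Zip list 3 of 22 rose adjusted over the list alone, among them LOC_Os08g36220 by 0.83 on the log2 scale. The cytokinin and clock calls ended without coleoptile white light replicate 1 (adjusted p = 0.0876 for both), and the expansin list was called upward (median 0.23, adjusted p = 0.0357 against 0.130 with all libraries, and adjusted p = 0.834 with an estimated correlation). Median, mean and camera direction differed in sign for auxin synthesis and transport, photosynthesis and flavonoid genes, none of them called. For the 15 lists not called, camera gave adjusted p from 0.0978 to 0.993.

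**Figure D4:**
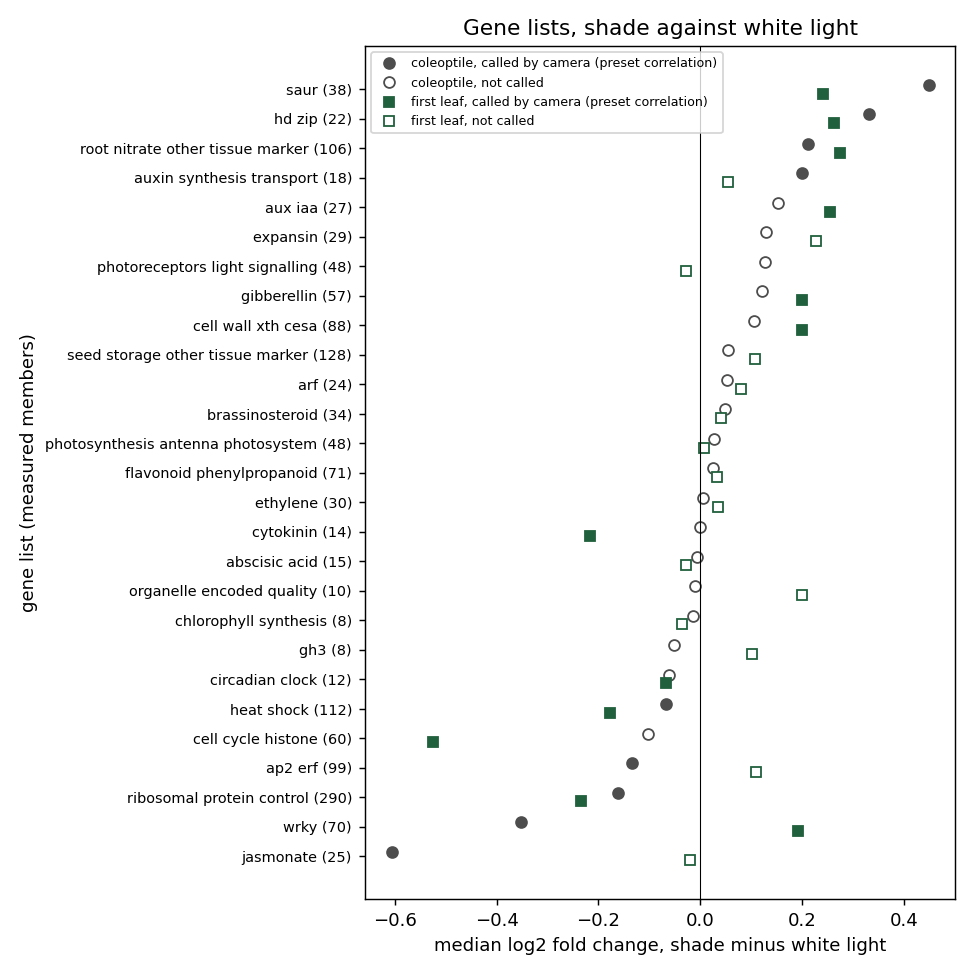
Median log2 fold change (shade minus white light, horizontal axis) of 27 gene lists, with the number of measured members in brackets; circles are the coleoptile, squares the first leaf, and filled symbols lists called by camera with its preset correlation. Medians run from -0.61 (jasmonate, coleoptile) to 0.45 (SAUR, coleoptile), and 0 of these calls held with an estimated correlation.

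Phytochromes, the red and far-red light receptors, did not pass in any comparison. In the coleoptile the log2 changes with shade were 0.11 ± 0.29 (SE) for phytochrome A (LOC_Os03g51030), 0.18 ± 0.20 for phytochrome B (LOC_Os03g19590) and 0.09 ± 0.18 for phytochrome C (LOC_Os03g54084). In the first leaf they were 0.21 ± 0.29, 0.55 ± 0.20 and 0.22 ± 0.18. Limma adjusted p ran from 0.802 to 1 over these 6 values. Of the light signalling genes given by identifier, 15 were tested and 0 passed in either tissue, and the same was found for 12 clock and 15 gibberellin genes.

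Whether the tissues responded differently was tested as the difference of the 2 shade responses, first leaf minus coleoptile, and 4 loci passed. Aldehyde dehydrogenase LOC_Os02g49720 was at 32.4 ± 2.43 FPKM in shaded and 8.01 ± 1.31 in white light first leaves, and at 8.44 ± 1.06 and 16.9 ± 0.932 FPKM in the coleoptile (SD, n = 2). Its difference of responses was 2.82 on the log2 scale (limma adjusted p = 0.0480). The 3 others are LOC_Os10g31530, LOC_Os10g31680 and LOC_Os10g31670 of the chromosome 10 stretch, on only in the shaded coleoptile (adjusted p = 0.0440, 0.0440 and 0.0480). LOC_Os07g04410, the P450 annotated as 90C1, was listed at 0 in the shaded coleoptile and the white light first leaf and was at 3.29 and 1.85 FPKM in the white light coleoptile and 3.36 and 2.83 FPKM in the shaded first leaf (adjusted p = 0.0656). Other large differences among the 50 smallest p-values were those of LOC_Os10g31660 (-5.25), LOC_Os02g44230 (4.601, a transcript with a conserved upstream reading frame) and the universal stress proteins LOC_Os03g19270 (3.79) and LOC_Os05g28740 (3.78), with adjusted p from 0.103 to 0.176. The expressed proteins LOC_Os04g54610, listed at 0 in the shaded coleoptile and the white light first leaf, and LOC_Os10g29159, listed at 0 in the white light coleoptile, had adjusted p = 0.292 and 0.170. There were 1173 loci at an unadjusted p under 0.05 (765 higher, 408 lower), where 1051 would pass by chance. The called loci split the other way, with 1 higher and 3 lower, and with quantile normalization 2 higher and 3 lower. The called count was 52 without coleoptile white light replicate 1, 887 without replicate 2 and 0 without any of the 6 other libraries, and the 4 loci remained without either white light coleoptile library. Limma called 0 loci with a pseudocount of 0.1 or a mean of at least 5 FPKM and 39 with no filter.

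Camera called 6 lists for this difference. WRKY (median 0.73, adjusted p = 8.90e-11), jasmonate (0.71, adjusted p = 1.85e-06) and AP2 genes (0.23, adjusted p = 1.85e-06) had higher responses in the first leaf, and many members of these families were over 2-fold higher in coleoptile white light replicate 1. Cell cycle and histone genes (median -0.39, adjusted p = 0.00245), light signalling genes (-0.25, adjusted p = 0.00480) and heat shock genes (-0.12, adjusted p = 0.0467) had lower ones. With an estimated correlation the WRKY, jasmonate, AP2 and heat shock lists had adjusted p = 0.604, and the 2 others adjusted p = 0.994. Without that library the light signalling (adjusted p = 0.115) and heat shock (adjusted p = 0.129) calls ended. The WRKY (median 0.42, adjusted p = 4.89e-06), jasmonate (0.46, adjusted p = 0.00864), AP2 (0.22, adjusted p = 0.00719) and cell cycle (-0.79, adjusted p = 1.56e-08) calls held, each with adjusted p = 0.868 with an estimated correlation. Aux/IAA, cytokinin, abscisic acid, photosynthesis, ribosomal and organelle-encoded lists were called in that fit and not with all libraries, also with adjusted p = 0.868 with an estimated correlation. Quantile normalization called the ribosomal (adjusted p = 0.0273) and GH3 lists (adjusted p = 0.0212). With all libraries, 0 list members passed over all loci, and without that library 2 AP2 genes and 1 seed list gene were higher and 1 abscisic acid gene, 1 cell wall enzyme and 2 seed list genes lower. Adjusted over the list alone, 1 light signalling gene was higher and 5 lower, 2 clock genes, 2 expansins and 1 heat shock gene were lower, and 1 cell wall enzyme was higher and 1 lower. For the 21 lists not called, camera gave adjusted p from 0.0747 to 0.994. Median, mean and camera direction differed in sign for auxin response factor, brassinosteroid, ethylene, HD-Zip, clock, expansin, flavonoid, seed and root lists. Across the 21014 loci the responses of the tissues correlated at Pearson r = 0.18 and Spearman rho = 0.26 (genes are not independent replicates, and the contrasts share no library). Without that library r was 0.09 and rho 0.08. Calls shared by the tissues in that fit cannot be set against independent lists. Each locus has 1 estimate of spread for both contrasts, so a small one favours a call in both.

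First leaf and coleoptile in white light differed at 2303 loci, 1245 higher and 1058 lower in the first leaf. The largest decreases among loci with a named function were as follows. The thionins, small antimicrobial peptides, THION3 (LOC_Os06g31890), THION6 (LOC_Os06g32020) and THION7 (LOC_Os06g32160) averaged 570, 488 and 646 FPKM in the coleoptile and at most 0.128 FPKM in the first leaf (limma adjusted p = 3.44e-06, 1.26e-06 and 4.01e-06). Glycine-rich protein LOC_Os02g37490 (log2 change -10.79), lipoxygenase LOC_Os03g52860 (-9.06), of the oxylipin pathway, and hydrolase LOC_Os03g62060 (-8.23) were also lower. Loci highest in the first leaf were a cupin protein (LOC_Os08g13440, 6.198), a helix-loop-helix factor (LOC_Os01g72370, 5.33), a carboxyl methyltransferase (LOC_Os06g20920, 4.94), a terpene synthase (LOC_Os08g04500, 4.71), an acyltransferase (LOC_Os02g37700, 4.59) and 9-cis-epoxycarotenoid dioxygenase LOC_Os02g47510 (4.52), which starts abscisic acid synthesis, with adjusted p from 0.000207 to 0.00544.

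Of 48 photosynthesis genes, 8 were higher and 0 lower in the first leaf (16 and 0 adjusted over the list alone), among them the Rubisco small subunit LOC_Os12g17600 (3991 ± 330 against 860 ± 46.5 FPKM, SD, n = 2), photosystem II protein W LOC_Os05g43310 and chlorophyll a/b binding protein LOC_Os02g52650. Camera called the list (median 0.80, adjusted p = 3.47e-09). It had adjusted p = 0.991 with an estimated correlation. Without coleoptile white light replicate 1 the median was 0.48 (adjusted p = 0.00156, and adjusted p = 0.968 with an estimated correlation), with 7 higher and 1 lower. Of 29 expansins, 3 were higher and 6 lower, including LOC_Os10g40700 at 1067 ± 792 FPKM in the coleoptile and 31.9 ± 4.01 in the first leaf. Cell wall enzymes had 4 higher and 14 lower of 88, and 18 higher and 15 lower without that library. In light signalling 10 of 48 were higher, with phytochrome-interacting factor 4 (LOC_Os03g56950) at 1.55 on the log2 scale, and 8 lower, with B-box gene LOC_Os02g43170 at -2.41. GIGANTEA (LOC_Os01g08700), LOC_Os03g17570 and LOC_Os07g49460 were the 3 of 12 clock genes that were higher, and 0 were lower. Auxin genes went both ways, with 4 Aux/IAA genes higher and 7 lower of 27, including OsIAA12 (LOC_Os03g43410) at -3.57, and 8 SAUR genes higher and 3 lower of 38 (9 higher and 15 lower without that library). Higher and lower counts were 1 and 2 of 8 GH3 genes, 2 and 4 of 18 auxin synthesis and transport genes, 3 and 1 of 24 auxin response factors, 5 and 8 of 57 gibberellin genes (15 and 9 without that library), 3 and 2 of 34 brassinosteroid genes, 1 and 1 of 30 ethylene genes, 3 and 1 of 14 cytokinin genes and 4 and 0 of 15 abscisic acid genes. They were 2 and 3 of 22 HD-Zip genes, 12 and 10 of 71 flavonoid genes, 8 and 2 of 112 heat shock genes, 5 and 6 of 70 WRKY genes, and 0 and 0 of 8 chlorophyll synthesis and 10 organelle-encoded genes. Without that library they moved by over 1.5 times for Aux/IAA (2 and 10), auxin response factor (6 and 1), brassinosteroid (5 and 3), ethylene (2 and 1), flavonoid (21 and 11) and WRKY genes (10 and 6), 1 chlorophyll synthesis gene was lower, and the expansin and abscisic acid lists were called (adjusted p = 0.0269 for both, and adjusted p = 0.968 with an estimated correlation).

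Jasmonate genes (2 higher and 7 lower of 25, median -1.19, camera adjusted p = 0.000107), AP2 genes (4 higher and 12 lower of 99, median -0.44, adjusted p = 0.0129) and ribosomal protein genes (0 of 290, median -0.16, adjusted p = 0.0247) were called lower in the first leaf, and cell cycle and histone genes (0 of 60, median 0.52, adjusted p = 0.00514) higher. Each had adjusted p = 0.991 with an estimated correlation. Quantile normalization ended the ribosomal call (adjusted p = 0.655) and moved its median to 0.003. The seed and root lists differed in both directions, with 17 seed list genes higher and 18 lower of 128 and 14 root list genes higher and 20 lower of 106. Without coleoptile white light replicate 1 the AP2 (adjusted p = 0.388) and ribosomal (adjusted p = 0.888, with 2 genes lower) calls ended, the jasmonate median was -0.78 (adjusted p = 0.0269), and 9 cell cycle and histone genes were higher (median 0.90, adjusted p = 1.91e-06). Both lists had adjusted p = 0.968 with an estimated correlation in that fit. Seed list counts were then 25 and 21, and root list counts 21 and 31. Median, mean and camera direction differed in sign for Aux/IAA, cytokinin, abscisic acid, chlorophyll synthesis, heat shock and seed lists. For the 22 lists not called, camera gave adjusted p from 0.0977 to 0.999. The called count was 527 (289 higher, 238 lower) in a fit to the white light libraries only, 3804 and 4022 without coleoptile white light replicate 1 and 2, 741 and 796 without first leaf white light replicate 1 and 2, and 1512 and 1514 without coleoptile shade replicate 1 and 2. In the shade libraries the same comparison called 2164 loci, 1465 of them called in white light with the same direction, and 2195 of the 2303 white light calls had the same sign in shade.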

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

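Every test in this part that weighs an explanation was chosen after its result was seen. The shade responses of the tissues differed by a test of the difference itself (first leaf minus coleoptile) at LOC_Os02g49720, an aldehyde dehydrogenase, by 2.82 on the log2(FPKM + 1) scale. They also differed at LOC_Os10g31530 (-4.38), LOC_Os10g31670 (-3.48) and LOC_Os10g31680 (-3.73), where both white light coleoptile libraries were listed at 0, so that the pseudocount sets the size of these values and they are not folds. Camera with its preset correlation called the difference for the medians of WRKY (0.73), jasmonate (0.71), AP2 (0.23), cell cycle and histone (-0.39), light signalling (-0.25) and heat shock genes (-0.12), and 0 of these 6 calls held with an estimated correlation.

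Coleoptile white light replicate 1 stood apart, with 1841 loci over 2-fold above the mean of the 3 other coleoptile libraries. A scaling difference is excluded as the whole cause, since 1640 of them stayed over 2-fold higher after scaling to equal medians. First leaf RNA in the library is excluded as the whole cause too, since 1534 lay above all 4 first leaf libraries, which mixing cannot give. A part from it is not excluded. Replicate 2 shared a part: 1750 loci over 2-fold higher in white light replicate 1 than in shade replicate 1 were picked. Their median was 0.41 in white light replicate 2 minus shade replicate 2, above the highest of 1000 random lists (0.0334). The 675 loci picked as lower had a median of -0.069. In the first leaf, the loci picked as higher had a median of 0.078 for white light minus shade. Random lists were drawn locus by locus, so any loci that vary together could exceed them. Whether the shared part is a response to light therefore cannot be told. Wounding or handling of that sample was not tested, and no label bears on it.

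Loci on only in the shaded coleoptile lay together on chromosome 10, with 7 of the 13 that reached 3 FPKM inside a window of 24 loci, the length of the stretch. The highest number in 10000 random draws, which treat the loci as independent, was 3 (permutation test, p = 1e-04, the smallest these draws can give). The window was sized on the stretch seen in these data, and 12 of its 24 loci are annotated as glycine-rich. The draws therefore argue only against separate, independent loci, and do not bear on similar neighbouring copies coming on together. Whether reads of 1 copy were shared among similar loci, which would make them fewer events than 7, cannot be told: the SD of their log2 replicate ratios was 0.47, against 0.50 for 9610 genes in the same range of level. Root RNA in the shaded samples may contribute. Of 46 root list loci under 0.5 FPKM elsewhere, 3 reached 0.5 FPKM there, against 109 of 7804 other loci outside the stretch (Fisher exact p = 0.0275). All 3 are annotated as peroxidases, a family that shoots also express, and 0 were among the 13 at 3 FPKM. Peroxidase LOC_Os05g04440 missed that bound in 1 library (2.98 and 19.0 FPKM). The root list also had a positive median with shade in the first leaf (0.28, against 0.21 in the coleoptile). The difference of the 2 responses was not called (camera adjusted p = 0.944). Whether root cap cells were present cannot be told from the 5 of 7 root cap family loci highest in both shaded libraries, as that family was picked after its values were seen, and a response of the coleoptile to shade cannot be told from a difference in what was dissected, because the labels give no measure of tissue purity.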

How the results depend on the processing

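Named loci that passed were checked in the alternative fits. A check pairs a locus with a fit of the same data, so checks are not separate fits. The 6 named coleoptile loci that passed kept their direction in all 105 checks and stayed called in 54 of them. The 3 for the difference of responses kept theirs in all 49 checks and stayed called in 21, and the 77 for tissue in all 1374 and stayed called in 1267. Loci were named mostly among those whose libraries do not overlap. This nearly fixes the direction in advance, so a kept direction is no support. Depth in reads is not known, so what it limits could not be measured. In the order coleoptile shade, first leaf shade, difference of responses and tissue, calls were 9, 0, 4 and 2303. With a pseudocount of 0.1 they were 0 for coleoptile shade and 0 for the difference. With no filter they were 68, 14 and 39 for the first 3, and with a mean of at least 5 FPKM 0, 5 and 0, where other genes were tested. First leaf calls were 14 with quantile normalization and 12 with equal medians, and difference calls were 7 with no trend. A fit to only the libraries compared, with fewer samples, gave 0 for coleoptile shade and 527 for tissue. Library weights, added after the data were seen, gave 3, 37, 0 and 1348. The tissue calls then split into 666 higher and 682 lower in the first leaf, against 1245 and 1058 without weights. Both libraries of a group got the same weight, 0.352 for each white light coleoptile library. The weights therefore act on groups and could not lower coleoptile white light replicate 1 alone. Except where stated, the cause was not tested.

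With a replicate block, calls were 1 for coleoptile shade and 0 for the difference of responses. The deviations of same-numbered libraries correlated at 0.0319 in the coleoptile and 0.0854 in the first leaf, so no large effect shared by number was seen. With 2 libraries per group this cannot tell whether same-numbered samples were handled together, and the labels do not say. Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, gave 0 to 1739, 0 to 51, 0 to 887 and 741 to 4022 calls, and a correlation of the tissues' responses of 0.0566 to 0.244. List calls with an estimated correlation were 0 in each comparison. They were 0, 1, 0 and 0 with the directional test of fry and 6, 4, 3 and 23 with its mixed test. Without coleoptile white light replicate 1, added after the data were seen, 10 lists were called for the difference of responses, against 6.

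Phytochromes, none of which passed, changed sign when 1 library was left out. Phytochrome A (LOC_Os03g51030) ran from -0.26 to 0.47 for coleoptile shade, -0.015 to 0.44 for first leaf shade and -0.26 to 0.47 for the difference. Phytochrome C (LOC_Os03g54084) ran from -0.027 to 0.28 for the difference, and phytochrome B (LOC_Os03g19590) from -0.15 to 0.24 for tissue. The cause was not tested.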

Other observations

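The values in this part were computed after the data were seen, and the test of the mean shade response was chosen after its result was seen. Without coleoptile white light replicate 1, hormone lists in the coleoptile differed from those with all libraries. The median log2 change of 57 gibberellin genes with shade was 0.38, against 0.12 with all libraries. Gibberellin 20 oxidase 2 (LOC_Os01g66100) was at 1.83 and the receptor-like genes LOC_Os06g11135 and LOC_Os06g11130 at 1.71 and 2.18. For 15 abscisic acid genes the median was 0.95, against -0.006 with all libraries. The 128 seed list genes had a median of 0.17 and the 106 root list genes one of 0.16, against 0.05 and 0.21. Photosynthesis genes had a median of -0.38 and cell cycle and histone genes one of 0.43, against 0.03 and -0.10. All of these medians without replicate 1 rest on 1 white light coleoptile library.

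The mean shade response of both tissues called 6 loci, 3 higher and 3 lower, with all libraries. Mitochondrial heat shock protein LOC_Os02g52150 fell by a log2 change of -1.57 (limma adjusted p = 0.0396), with -1.43 in the coleoptile and -1.72 in the first leaf. Early light-induced protein LOC_Os07g08160 (-2.57) and expressed protein LOC_Os01g69890 (-1.29) also fell (adjusted p = 0.0476 for both), and the 3 higher loci are the chromosome 10 loci LOC_Os10g31530, LOC_Os10g31670 and LOC_Os10g31680. Their calls come from the coleoptile (4.56, 3.55 and 3.73, sizes set by the pseudocount), with 0.18, 0.07 and 0 in the first leaf. Of the 18 splits of the libraries within each tissue, 1, the real one, gave 6 calls and the highest other gave 5. With 18 splits no share can be under 0.05, so these are too few to exclude a chance division of the libraries.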
